A study of Homo sapiens with 6 samples.

How the data were processed

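The RNA probed was the human long noncoding RNA CONCR, made by in vitro transcription with the T7 system. RNA (3 pmol) was incubated for 30 min at 37 °C in 150 mM KCl, 50 mM HEPES at pH 7.4 and 5 mM MgCl2, and then treated for 6 min at 37 °C with 10 mM 1M7 or with its solvent DMSO, per the labels' protocols. 1M7 (1-methyl-7-nitroisatoic anhydride) acylates the 2'-hydroxyl of flexible nucleotides, and reverse transcription with SuperScript II in a manganese buffer (6 mM MnCl2 in the mix) turns the adducts into mutations of the cDNA. The labels' protocols name random nonamers for the reverse transcription, 1 PCR with a primer pair specific for the transcript (a 793 bp amplicon) and Nextera XT libraries. The labels also carry a cell line, the teratocarcinoma line NT2, although the RNA probed was synthetic.

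The deposited data are 3 tables, 1 per replicate number, each setting a 1M7 library beside the DMSO library of that number over the 768 nucleotides of the RNA. The mutation counts and the read depths are deposited counts per nucleotide without normalization, per the file headers. The mutation rate is a deposited fraction, the mutation count divided by the effective depth (the reads in which a mutation at that nucleotide would have been called). The difference of the 1M7 and DMSO rates and the normalized reactivity are scores that the authors deposited, and the normalized score was the rate difference multiplied by 1 factor per table, 156.0, 148.7 and 164.0 for replicates 1, 2 and 3, read off from the ratio of both columns. How that factor was set, the read aligner, the mutation caller and its version are not given in the sources used here, and no genome build is named. Of the columns of each table, 6 were not used, 4 of a denatured control and 2 of standard errors of unnormalized values.

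Samples were grouped by the treatment in their labels, 3 libraries with 1M7 and 3 with DMSO. The labels do not say whether the replicates came from separate transcription or folding reactions. The p-values of edgeR, DESeq2 and the permutation test therefore measure the spread between these libraries, which may be technical. Libraries of a group differed by more than sampling noise (chi-square over degrees of freedom 1.50 to 3.18 over nucleotides) and were counted separately. The sequence of the reverse PCR primer (28 nt) matches the last 24 nucleotides of the tables, 745 to 768, and these were kept out of the comparisons in the report; a separate test of the site and the alternative without filters used them. The measured region was nucleotides 1 to 744, all with an effective depth of at least 1000 in every library and a DMSO rate of at most 5% in every DMSO library. The region was divided into 3 segments (5', middle and 3') of 248 nucleotides. Nucleotides 1 and 2 had no mutation in any library and were not tested singly, which left 742. At their depths this allows rates of up to 0.00418% and 0.00402% (3 counts over the lowest depth), if mutations there could be read at all. Both stayed in the profile, the classes and the folding as unreactive.

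Rates per nucleotide were compared with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3) on the mutation counts with the log effective depth of each nucleotide and library as the offset, without further scaling, since a reagent is meant to raise most nucleotides, and with Benjamini-Hochberg adjustment over nucleotides at 0.05. Standard errors (SE) of log2 ratios come from the same fit. The rate of a whole library was its summed mutations over its summed effective depth, and groups were compared with a two-sided exact permutation test, whose smallest p for 3 against 3 libraries is 0.1. Statistics of the profile along the RNA were tested against all 744 rotations of the profile (two-sided, exact over rotations, smallest p 0.00134), which keep the similarity of neighbouring nucleotides. The 3 rotation tests planned were adjusted together by Benjamini-Hochberg. The profile was the mean normalized reactivity of the 3 replicates, and windows were medians over 51 nucleotides.

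Structures were computed with ViennaRNA 2.7.2 at 37 °C, from sequence alone and with Deigan pseudo-energies (slope 1.8, intercept -0.6 kcal/mol) from the mean profile and from each replicate. For folding, negative reactivities were set to 0 and the primer site was given no reactivity. The sequence folded was that of the tables, without the vector-derived leader that the forward primer binds. The Shannon entropy of a nucleotide was taken in bits over its pairing probabilities. The entropy therefore counts alternative partners and not the unpaired state. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and DESeq2 1.42.0 were also used.

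The design, the rule for naming nucleotides and regions, and the alternatives not said to be added were fixed before the data were examined. The rule took the 15 nucleotides with the highest mean reactivity among those past the threshold and higher in 1M7 in all 3 same-numbered pairs, up to 5 past the threshold with a lower rate in 1M7, the 5 with the highest DMSO rate, the 3 lowest and the 3 highest windows (not overlapping within each set), the 3 helices with the most consecutive pairs, and up to 5 longest regions of at least 20 nt in which windowed reactivity and entropy both lay below their medians. It also fixed groups: bases, segments, paired, unpaired and hairpin-loop nucleotides of the sequence-only structure, guanine runs, G-quadruplex motifs with runs of 2 or more guanines, and the primer-derived ends. Ties in helix length were broken by 5' position. Anything named outside the rule is said to be so.

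The edgeR step was tested on simulated counts for the 742 nucleotides in 10 runs with 200 changed nucleotides each. It recovered 97.6% of 1.5-fold, 45.6% of 1.2-fold and 12.2% of 1.1-fold increases and 57.2% of decreases to 0.8-fold, and 3.10% of its calls were false. The simulated counts varied independently between nucleotides, with no shift of a whole library. The real DMSO libraries had rates of 0.209%, 0.200% and 0.229%, so these shares, false calls included, need not hold for the data. The rotation test, on simulated profiles of 744 nucleotides, called 6.50% of 200 runs without a difference, 35.5% with a 3' segment at 0.75 of the rest and 95.5% at 0.5 of it. The known structure of the folding test was the model directed by the mean profile of these same data. The test is therefore no benchmark on an independent structure. Folding with reactivities simulated for that model, at means of 1 for unpaired and 0.1 for paired nucleotides, recovered 93.8% of its pairs, against 41.4% from sequence alone. At the smaller contrasts measured here, a simulation added after seeing the data, it recovered 77.0% (52.7% to 90.5% over 10 runs) with the means of the mean-profile model, 0.864 and 0.332, and 53.0% (31.4% to 66.4%) with those of the sequence-only structure, 0.712 and 0.477.

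Median effective depths per nucleotide lay between 168039 and 215214. The Wilson 95% interval of a library's rate spanned, for 1M7 replicate 1, 0.567% to 0.570%. Such intervals take reads as independent and hold no spread between libraries. The labels name no molecular identifiers for the PCR reads, so the intervals may not cover even the counting error. Alternatives covered the test, the offset, the scaling, the filters, the background, the windows, the folding parameters and each library left out. Gene names were taken from a RefSeq gene table of assembly GRCh38.p14, whose coordinates were used only to find the neighbouring genes.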

Results

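CONCR is a human long noncoding RNA on chromosome 12, listed as DDX11-AS1 (synonyms CONCR and SCAT4) between TSPAN11-AS1 and DDX11 in the gene table of assembly GRCh38.p14. DDX11 encodes a DNA helicase that acts in sister chromatid cohesion, and the series title places a structural domain at the 3' end of CONCR. SHAPE-MaP, in which mutations in cDNA read out nucleotides acylated by 1M7, was carried out on the in vitro transcribed RNA. There were 3 libraries with 1M7 and 3 with the solvent DMSO. Positions are counted from 1 at the first nucleotide of the deposited sequence, and 744 nucleotides upstream of the reverse primer site were measured. Median effective depths were 168039, 189085 and 208287 reads in 1M7 replicates 1, 2 and 3 and 196243, 187396 and 215214 in the DMSO replicates.

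The first comparison asked how far 1M7 raised mutations over the solvent. The mutation rate was 0.570% ± 0.00565 with 1M7 and 0.213% ± 0.0152 with DMSO (SD, n = 3 each), a ratio of 2.68. All 3 libraries with 1M7 lay above every DMSO library, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allows. The DMSO libraries had rates of 0.209%, 0.200% and 0.229%. Adenines showed the largest ratio of summed rates, 6.39 ± 0.189, followed by uridines with 2.97 ± 0.238, guanines with 2.17 ± 0.211 and cytidines with 1.79 ± 0.136 (SD, n = 3). The DMSO rate was lowest at adenines, 0.0938% ± 0.00331, and highest at guanines, 0.329% ± 0.0266 (SD, n = 3).

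**Figure D1:**
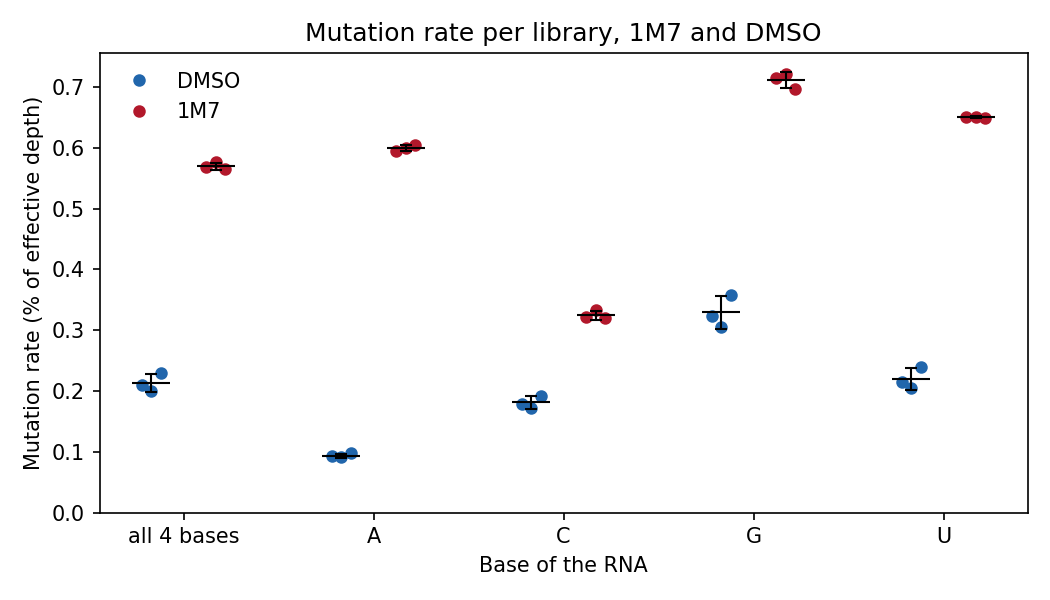
Mutation rate (y axis, % of effective depth) of each library, over all bases and at A, C, G and U (x axis). Points are libraries, horizontal bars with whiskers the mean and SD of 3 libraries; all 1M7 points lie above the DMSO points of the same base, and the gap is narrowest at C, where the rates are 0.324% and 0.181%.

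At the level of single nucleotides, 733 of 742 had a higher rate with 1M7 by edgeR's quasi-likelihood test, and 732 were higher in all 3 same-numbered pairs. No nucleotide was called lower: edgeR gave 0, also 0 at an unadjusted p under 0.05, and DESeq2 and Fisher's exact test on summed counts gave 0, with 725 and 739 higher. The median ratio over nucleotides was 2.35, with quartiles of 1.63 and 4.68. The 9 nucleotides that missed the threshold were U220, G310, A474, C545, C577, C641, C711, C714 and U743, listed after their values were seen, 5 of them cytidines. Scaling each library to its typical nucleotide (TMM) shifted the median log2 ratio from 1.23 to 0.00, so that 329 nucleotides stood above and 327 below the typical increase. Those counts measure departure from the common increase and not a loss of mutations.

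The most reactive nucleotide was A142 in the sequence GUGUGAGAUUA (137 to 147), with a normalized reactivity of 4.77 ± 0.201 (SD, n = 3). Its mutation rate was 3.31% with 1M7 and 0.251% with DMSO, a log2 ratio of 3.71 ± 0.08 (SE, edgeR adjusted p = 1.67e-23). A35 followed with a reactivity of 4.52 ± 0.326, and its rate rose 50.6-fold, more than that of any other nucleotide tested, from 0.0581% to 2.95%. A251 reached 4.44 ± 0.123, U222 4.03 ± 0.235 and its neighbour A223 3.97 ± 0.214. The others of the 15 most reactive were A412, A313, A737, G264, G324, A366, G212, G141, A45 and G340, the last with a reactivity of 2.70 ± 0.0428 (SD, n = 3). Among the 15, 9 were adenines, 5 guanines, 1 a uridine and 0 cytidines, while adenines made up 21.5% of the measured nucleotides. In position, 7 lay in the 5' segment, 7 in the middle segment and 1, A737, in the 3' segment. The sequence-only structure left 10 of the 15 unpaired.

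G256 had the highest DMSO rate, 3.20% ± 0.106, against 4.29% ± 0.150 with 1M7 (SD, n = 3; log2 ratio 0.42 ± 0.06, SE). C577 came next with 2.41% ± 0.0881 in DMSO and 2.59% ± 0.0999 with 1M7, a log2 ratio of 0.10 ± 0.06 (edgeR adjusted p = 0.0975), and it passed the threshold once DMSO replicate 3 was left out (0.13, edgeR adjusted p = 0.00475) and in Fisher's exact test on summed counts (0.10, adjusted p = 4.23e-12), which ignores the spread between libraries. G264, at 2.24% in DMSO and 4.54% with 1M7, was also among the 15 most reactive. G310 had 1.65% and 1.68%, a log2 ratio of 0.02 ± 0.07, and G408 1.62% and 2.42%, a log2 ratio of 0.57 ± 0.06.

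Replicate profiles of normalized reactivity correlated across the 744 nucleotides with Pearson r = 0.994 (replicates 1 and 2), 0.988 (1 and 3) and 0.982 (2 and 3), and Spearman rho was 0.980, 0.957 and 0.942. Nucleotides of 1 RNA are not independent replicates, so no p is given. A reactivity below 0.4 was found at 56.9% ± 1.95 of nucleotides, 0.4 to 0.85 at 24.4% ± 1.62 and above 0.85 at 18.7% ± 0.356 (SD, n = 3). The class was the same in all 3 replicates for 652 nucleotides, 87.6% of them. Without subtraction of the DMSO rate, 31.2% of nucleotides were below 0.4 in the mean profile. Values were higher there (median 0.616 in place of 0.287 at paired nucleotides of the sequence-only structure), so the fixed limit is not an equal measure.

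Reactivity differed by base. The median normalized reactivity was 0.515 ± 0.00854 at U, 0.462 ± 0.0211 at A, 0.353 ± 0.0567 at G and 0.156 ± 0.0182 at C (SD over 3 replicates). In the mean profile the spread between the highest and lowest base median was 0.347, above all other rotations of the profile along the sequence, whose highest value was 0.273 (exact rotation p = 0.00134, the smallest possible, adjusted p = 0.00202). Of 203 cytidines, 176 had a reactivity below 0.4 and 7 one above 0.85, while 45 of 160 adenines were above 0.85. Cytidines had the lowest median except on the ratio scale (rescaled log2 of 1M7 over DMSO), where the medians were 0.203 at G and 0.212 at C, and adenines then had the highest, 0.781. Without subtraction of the DMSO rate the highest median was that of G, 0.866.

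Guanines in runs of 2 or more (103 nucleotides) had a median reactivity of 0.286 ± 0.0557 and single guanines (107) one of 0.496 ± 0.0661 (SD, n = 3), with the single guanines higher in each of the 3 replicates. The difference was not tested. They were also higher on the ratio scale (0.258 and 0.144) and without subtraction (1.07 and 0.768). There were 3 non-overlapping G-quadruplex motifs with runs of at least 2 guanines. At 72 to 98 (GGGAACUGGGCACGCGGGAACCCAGGG) the median was 0.315 over guanines of the runs and 0.291 over the other nucleotides, at 558 to 583 it was 0.184 and 0.345, and at 648 to 673 it was 0.421 and 0.270.

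The title of the series raises the question whether the 3' end stands apart. The median reactivity was 0.338 ± 0.0358 in the 5' segment (1 to 248), 0.300 ± 0.0301 in the middle segment (249 to 496) and 0.345 ± 0.0173 in the 3' segment (497 to 744; SD, n = 3). The 3' segment exceeded the rest by 0.0248 in the mean profile and by 0.0174, 0.0242 and 0.0392 in replicates 1, 2 and 3, within the range of rotated profiles (exact rotation p = 0.551, adjusted p = 0.551). The segments differed in composition, with 63.7%, 58.5% and 44.4% G and C from 5' to 3'. On the ratio scale the difference was 0.136 with an exact rotation p of 0.00269, and after division by the median of each base it was -0.128 (exact rotation p = 0.538), so its sign and its call depended on the scale.

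In 51-nt windows the median of the mean profile ranged from 0.209 to 0.551. Windows were ordered by that median, and the values with an SD below are means of the replicate medians. The lowest window was 331 to 381, with 0.225 ± 0.0380 (SD over 3 replicates), 70.6% G and C and 22 cytidines. Its sequence is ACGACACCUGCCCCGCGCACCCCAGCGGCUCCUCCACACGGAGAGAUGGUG. In the mean profile its median was 0.209, that of 414 to 464 was 0.232 and that of 645 to 695 was 0.253. Over replicates these were 0.219 ± 0.0138 for 414 to 464 and, in the 3' segment, 0.273 ± 0.0295 for 645 to 695. The highest window, 290 to 340, had a median of 0.519 ± 0.0244, overlapped the lowest by 10 nucleotides and reads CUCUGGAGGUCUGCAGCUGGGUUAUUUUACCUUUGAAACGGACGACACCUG. It was followed by 99 to 149 with 0.441 ± 0.0778 and 3 to 53 with 0.475 ± 0.0944 (SD, n = 3; 0.462 and 0.452 in the mean profile). Of 694 window centres 1, nucleotide 356, lay at least 0.1 below the median of the whole profile (0.324), a share of 0.144%; in single replicates the share was 5.33%, 2.16% and 0.144%. This share depended on the settings, with 4.47% without replicate 3, 7.28% in 31-nt windows, 9.80% on the ratio scale and 13.7% without DMSO subtraction. Without subtraction values were higher, so the fixed gap of 0.1 is not an equal measure there. The order of windows depended on the scale. On the ratio scale 645 to 695 had a median of 0.416, above the 0.393 of 290 to 340, the 0.356 of 99 to 149 and the 0.320 of 3 to 53. Without subtraction 3 to 53 (1.06) and 99 to 149 (1.03) exceeded 290 to 340 (0.783). There 414 to 464 (0.480) and 645 to 695 (0.498) lay below 331 to 381 (0.502).

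**Figure D2:**
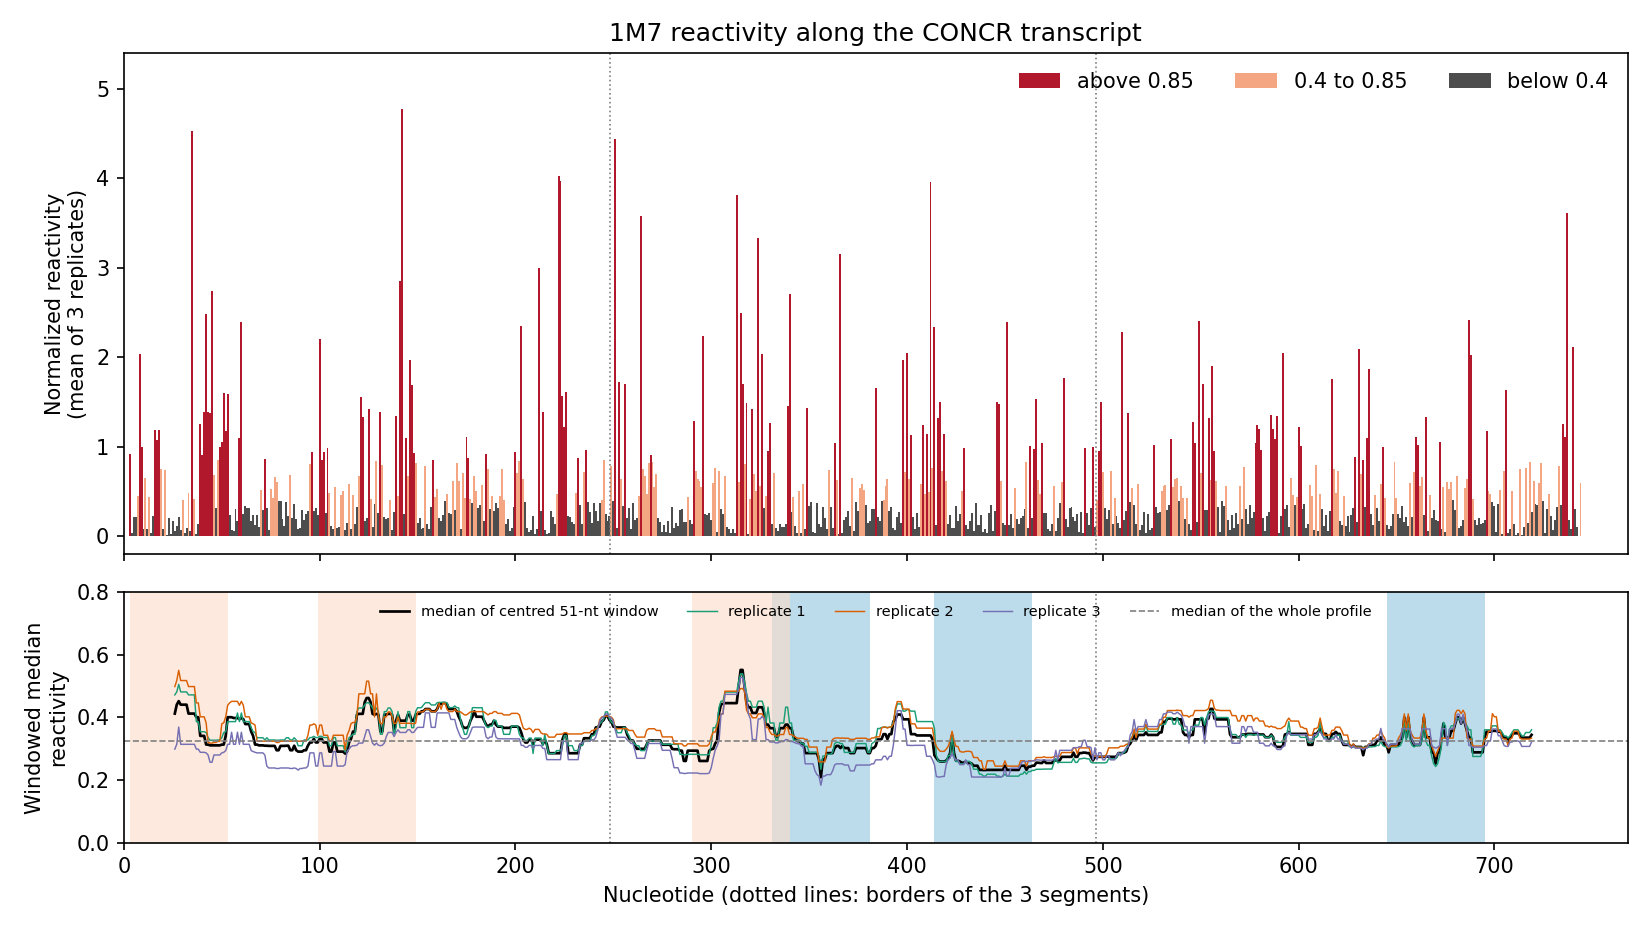
Mean normalized reactivity of 3 replicates at each nucleotide (upper panel, colours give the classes below 0.4, 0.4 to 0.85 and above 0.85) and the median of the centred 51-nt window (lower panel, black for the mean profile, colours for replicates), against position in the RNA. Blue bands mark the 3 lowest and orange bands the 3 highest windows; the windowed median falls to 0.209 near nucleotide 356 and rises to 0.551 in the window 290 to 340.

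Reactivity was set against the minimum free energy structure predicted from sequence alone (-275.6 kcal/mol, 255 base pairs), which used no reactivities. Unpaired nucleotides (244) had a median of 0.436 ± 0.0116 and paired nucleotides (500) one of 0.286 ± 0.0306 (SD, n = 3). The 90 nucleotides in hairpin loops had 0.550 ± 0.0446 and other unpaired nucleotides 0.424 ± 0.0106. The area under the ROC curve for unpaired over paired nucleotides was 0.610, with 0.608, 0.595 and 0.626 in the single replicates, above every rotation, of which the highest gave 0.579 (exact rotation p = 0.00134, adjusted p = 0.00202). It was 0.640 ± 0.0107 in the 5' segment, 0.589 ± 0.0160 in the middle segment and 0.598 ± 0.0198 in the 3' segment (SD, n = 3). Unpaired medians exceeded paired ones at each base, with 0.609 against 0.374 at A, 0.213 against 0.135 at C, 0.588 against 0.315 at G and 0.586 against 0.477 at U as means of 3 replicates. With the 1M7 rate alone, without subtraction of DMSO, the area was 0.541 and no longer past the threshold (exact rotation p = 0.0685).

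The structure directed by the mean profile had 220 base pairs, of which 91 (41.4%) were in the sequence-only structure. In the replicate models that share was 42.4% ± 1.24 (SD, n = 3). The mean-profile model paired 62.5% of the 5' segment, 53.6% of the middle segment and 58.9% of the 3' segment, and the replicate models 60.3% ± 1.91, 51.2% ± 2.13 and 58.3% ± 1.42 (SD, n = 3). The median Shannon entropy was 0.613 ± 0.0165, 0.622 ± 0.00217 and 0.489 ± 0.0653 bits (SD, n = 3) in the 5', middle and 3' segments, a difference that was not tested. The nucleotides that the mean-profile model left unpaired had an area of 0.746, which is no independent measure because the model used the same reactivities.

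The replicate models differed in their pairs. All 220 pairs of the mean-profile model were in the replicate 1 model, 113 in that of replicate 2 and 115 in that of replicate 3, and 110 (50.0%) in all 3. This share depended on the settings, with 88.3% on the ratio scale, 89.3% without DMSO subtraction and 85.3% in maximum expected accuracy structures. It was 32.4% under the stricter filter (depth at least 5000, DMSO rate at most 2%), which kept 741 of 744 nucleotides. The lowest depth was 64668, so only the DMSO limit removed nucleotides, namely G256, G264 and C577. Replicates 2 and 3 shared 197 pairs, 94.7% of those of replicate 2. Of the 32 helices with at least 4 pairs in the mean-profile model, 18 were whole in all 3 replicate models, 10 of them within the 3' segment (1 of these, 738 to 743 with 748 to 753, pairs into the primer site), 4 within the 5' segment and 3 within the middle segment. The remaining one joined nucleotides 3 to 8 (GCAUGC) with 729 to 734 (GCAUGC). The distribution over segments was not tested and holds for these models only. The 3' segment had an excess of nucleotides with the same partner, or unpaired, in all replicate models. This excess (31.9 percentage points, chosen after seeing the data) became -14.9 on the ratio scale and -12.5 without subtraction.

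Of the 3 helices with the most consecutive pairs, that of nucleotides 23 to 29 with 61 to 67 (7 pairs) was in all replicate models, in the sequence-only structure and in the mean-profile models of all 10 other settings of background, filter, folding parameters and replicates left out. That of 160 to 166 with 238 to 244 (7 pairs) was, of the replicate models, in that of replicate 1 only and in 7 of the 10 settings. The helix between nucleotides 3 to 8 and 729 to 734 (6 pairs, 1 of several of that length) was in all replicate models and 8 of the settings but not in the sequence-only structure. The setting with a span of at most 300 nt could not hold this helix. In the 3' segment, and chosen after the models were seen, a stem with arms at 514 to 528 and 663 to 678 held helices of 4, 6 and 4 pairs, all in each replicate model and in the sequence-only structure. Its central helix, CCUCAC at 519 to 524 with GUGAGG at 668 to 673, had a median reactivity of 0.174 and was in all 10 settings. The inner helix (median 0.292) was also in all 10, while the outer one, AAUC with GAUU, had a median of 0.454 and was in 7. Paired nucleotides of the sequence-only structure had medians of 0.378 at A and 0.468 at U in the mean profile and unpaired ones 0.589 and 0.596, so the outer value does not tell pairing from its absence. A single region, 346 to 384 in the middle segment, had both windowed reactivity and windowed entropy below their medians over at least 20 nt. Its reactivity was 0.290 ± 0.0428 (SD, n = 3), its median entropy 0.0160 bits, and 59.0% of its 39 nucleotides were paired.

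**Figure D3:**
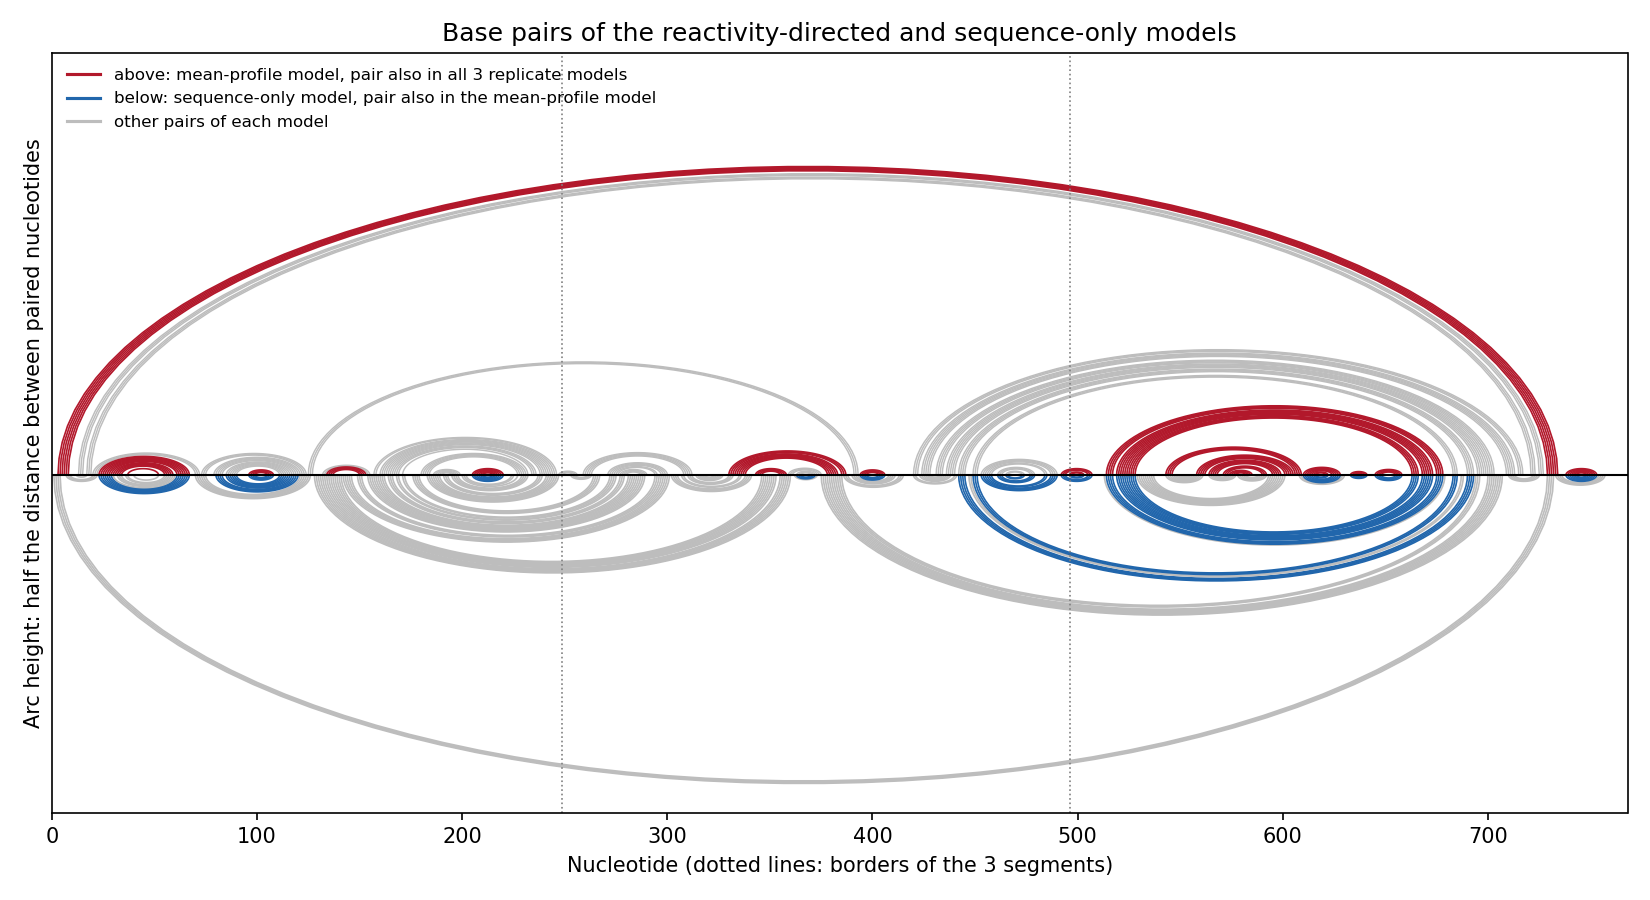
Arcs join paired nucleotides along the RNA (x axis, nucleotide), above the line for the mean-profile model (220 pairs; red, the 110 also in all 3 replicate models) and below for the sequence-only model (255 pairs; blue, the 91 shared with the mean-profile model). Arc height is proportional to the distance between partners; the stem between 514 to 528 and 663 to 678 appears red above and blue below.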

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

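The test on the primer site below was chosen only after the result was seen. Within the site of the reverse PCR primer, which the comparisons of the report left out, 6 of 19 nucleotides with enough depth had a higher mutation rate with 1M7 than with DMSO in edgeR's test, and 0 had a lower one. The ratios were 2.06 at C745, 1.52 at C746, 6.87 at A747, 5.98 at A748, 2.69 at A750 and 2.03 at A752. The rates were low, 0.151% ± 0.0192 with 1M7 and 0.0219% ± 0.00232 with DMSO (SD, n = 3) at A747. Since bases within a primer come from the oligonucleotide, a candidate explanation is the replacement of the primer's 3' end by copied template, with the excess at the first 4 nucleotides (median log2 ratio 1.81), while the other 15 tested had a median of 0.27, and A750 and A752 lie beyond those 4. No biological explanation was tested.

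The difference between 1M7 and DMSO at single nucleotides was set against other divisions of the libraries. The 6 libraries can be divided into 3 and 3 in 10 ways, and 1 of them, the real one, gave 733 nucleotides past the threshold, while the highest of the others gave 0. The splits are too few for a share under 0.05. Each of the other divisions also held both treatments in both groups. The 1M7 effect then counted as spread within groups and left little room for calls, so the contrast with 0 is no further support.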

How the results depend on the processing

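The result on shared partners below, and its tests, were chosen after seeing the data. Of 119 alternative repeats of overall results, 21 moved, 7 weakened, 1 grew stronger and 5 reversed. The other 85 kept direction and side of the threshold or moved within a set allowance. Of 378 for single nucleotides, groups and windows, 336 kept theirs, 31 moved, 2 weakened, 2 grew stronger and 7 reversed. Some could not change side: a depth of 5000 removed nothing, and the permutation test cannot pass 0.05. Counts of higher nucleotides ranged from 554 (against a 1.5-fold increase, counted as kept) to 739 of 742. Without filters 740 of 765 were higher, 6 of 23 in the primer site. TMM scaling, the exception, measures departure from the typical nucleotide and gave 329 higher and 327 lower. Under it the log2 ratios of G264, G256, C577, G310 and G408 were -0.21, -0.81, -1.13, -1.21 and -0.66. With the replicate number as a block edgeR called 731 higher, and the ratio of rates within pairs was 2.68. The block lost the calls of C585 and G309 (adjusted p = 0.0593 and 0.0875 in edgeR) and changed no other. Deviations of same-numbered libraries from their group means correlated over nucleotides with r = 0.015, -0.073 and -0.115. These values show no shared deviation per nucleotide. A shift of a whole library does not enter r, so joint preparation stays open.

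On the ratio scale the 3' segment exceeded the rest by 0.136 (past the threshold), 9.80% of windows were low, 52.3% of model pairs were shared with the sequence-only structure and 88.3% were in all replicate models. Without DMSO subtraction these were -0.0529, 13.7%, 48.0% and 89.3%, the lowest replicate r was 0.997, 31.2% of nucleotides were below 0.4 and the area for unpaired nucleotides was 0.541. With 2 equal segments the 3' one minus the 5' one gave -0.0161, and division by base medians -0.128. With 31-nt windows 7.28% were low. The share of pairs in all replicate models was 32.4% with the stricter filter. It was 60.3% with slope 2.6, 58.3% with a span of at most 300 nt and 85.3% in maximum expected accuracy structures. It was 50.0% with 1 common DMSO background and 99.5% when only DMSO rates differed, both added after seeing the data. The share with the sequence-only structure was 45.8% under that span and 45.6% in expected accuracy structures. Why these values changed was not tested.

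The share of nucleotides with the same partner in all replicate models was 31.9 percentage points higher in the 3' segment than in the rest (exact rotation p = 0.0484), but -14.9 on the ratio scale, -12.5 without subtraction, 2.83 under the stricter filter, 14.3 with slope 2.6, 21.6 under the span and 8.67 in expected accuracy structures. Its sign and its call depended on the setting, and of the replicates left out it stayed past the threshold only without replicate 3.

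Leaving out 1 library or replicate gave 723 to 734 higher and 0 lower nucleotides, rate ratios of 2.597 to 2.787, base spreads of 0.334 to 0.357, lowest r of 0.982 to 0.994, 56.6% to 58.3% below 0.4, 3' differences of 0.0192 to 0.0312, low windows of 0.144% to 4.47% (the highest without replicate 3), areas of 0.603 to 0.618, 41.4% to 41.6% of pairs shared with the sequence-only structure, 50.0% to 52.5% in all replicate models, shared-partner differences of 5.24 (without replicate 1) to 30.8 and G310 log2 ratios of -0.0027 to 0.059. At these depths 45.6% of 1.2-fold increases were recovered in simulation, so smaller changes at single nucleotides can be missed.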

Other observations

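The cytidines of the 3' segment were nearly all of low reactivity, with 48 of 49 below 0.4, against 66 of 76 in the middle segment and 62 of 78 in the 5' segment. Adenines above 0.85 numbered 16 of 45 in the 5' segment, 14 of 53 in the middle segment and 15 of 62 in the 3' segment. These differences were not tested. The 6 pairs that close the RNA in all replicate models (nucleotides 3 to 8 with 729 to 734) had a median reactivity of 0.271. They bring the ends of the RNA together in the model. Their member C8 had a rate of 1.42% with 1M7 and 0.112% with DMSO. That ratio, 12.6, lies above the upper quartile of all nucleotides (4.68). The others of its arm had ratios of 1.23 (C4) to 4.37 (A5). The hairpin of 738 to 743 with 748 to 753 pairs with nucleotides of the primer site, where no reactivity was used.

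The replicate profiles correlate at 0.982 or above, and yet the models of replicates 2 and 3 share only 51.1% and 52.5% of the pairs of replicate 1. With 1 common DMSO background 50.0% of the mean-structure pairs were in all 3 models, as with separate backgrounds, and when only the DMSO rates differed 99.5% were (both alternatives chosen after seeing the data), which argues against different DMSO backgrounds as the whole cause; a part of the subtraction itself stays open, since without it 89.3% were in all 3 at a lowest r of 0.997, and since with the common background it was replicate 3 that stood apart (54.1% of the pairs of replicate 1) and no longer replicate 1 (95.5% in replicate 2). A candidate explanation is the nearly equal energy of alternative structures, since on the mean profile the replicate 2 and 3 structures cost 0.860 and 1.98 kcal/mol more than the minimum of -345.07 kcal/mol. Counting error stays open: over 100 redraws of replicate 1 within its deposited standard errors a median of 96.4% of its pairs was kept, but the 5th percentile was 50.7%, and 18 redraws kept under 70%. No biological explanation was tested.

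The low reactivity of cytidines could come from more frequent pairing of C. Among nucleotides unpaired with a probability above 0.9 from sequence alone, the median was 0.230 at 17 cytidines and 0.590 at 65 others, a ratio of 0.391, which argues against pairing as the whole cause as far as the prediction is right. A base preference of the reagent, or of the mutations it leaves, stays open and was not tested.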
